A study of Bos indicus x Bos taurus with 47 samples.

How the data were processed

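Gene expression was measured in muscle of 47 crossbred steers (Bos indicus crossed with Bos taurus, about 18 months old per the labels), with 1 array per steer. Per the labels, the muscle was longissimus cervicis, taken within 1 h of death and before any electrical stimulation of the carcass. RNA was extracted with TRI Reagent from 100 to 200 mg of tissue, and RNA with an integrity number above 8 was treated with DNase, column purified and labelled with Cy3 by Agilent's low input protocol, per the labels' protocols. Steers were grouped from the labels by the residual of Warner-Bratzler shear force, a measure of meat toughness, as high or low. The residual was that of electrically stimulated meat (ES) for 23 steers and of meat without stimulation (NES) for 24 steers. This gave 12 ES high, 11 ES low, 12 NES high and 12 NES low arrays, all from different steers.

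Each deposited scanner file held fluorescence intensity per spot in a single colour, extracted per the file headers with Agilent Feature Extraction 10.7.1.1 for 43 arrays and 10.7.3.1 for 4 arrays. The processed signal is the background-subtracted intensity, per the file headers. A separate deposited matrix held log2 values that the authors had made from the same arrays. Set against the scanner values, that matrix had a correlation of 0.994 to 1.00 and a slope of 0.994 to 1.00 on the log2 scale after centring of each probe, and the median of every probe was 0, so the authors' log2 values were centred on each probe's median. Its column medians ran from -0.19 to 1.97, so the arrays were not centred on a common median. The dim array NES high replicate 3 (median intensity 27.8) had 0.38 and the bright ES low replicate 2 (158) -0.16, the reverse of their intensities. Some scaling between arrays had therefore been applied, and which one stays unknown. The matrix had 43698 probe names, of which 43653 were probes of the arrays and 45 were not.

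From the scanner files, control spots and spots marked as outliers were left out and replicate spots of a probe were averaged, which gave 43653 probes from 43803 spots. The main values were log2 of the processed signal minus the log2 of each array's 75th percentile. A symbol was printed in the files for 1540 probes, and 898 more probes took the symbol of a probe with the same accession. In all 2438 probes carried 1496 symbols, as the array's design gave them. The median correlation of probes linked to 1 gene in this way was 0.429 over 641 pairs, against 0.011 for 1000 random pairs. Of the symbols, 1060 (70.9%) were found in the reference table of cattle genes and 0 accessions were, so all other probes kept the name in the file. The arrays' design was made on cattle assembly Btau_3.1, per the file headers, and no genome positions were used here. Each gene was represented by its brightest probe, and genes or unnamed probes were kept where they were well above background in at least 50% of the arrays of at least 1 group.

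Each of 5 contrasts was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 4 groups in 1 fit: high minus low in the ES set, high minus low in the NES set, the mean of both, their difference, and ES set minus NES set. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and all tests were 2-sided. Fixed lists of genes (26) and of cell type markers (11) were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, and with an estimated correlation, fry and a permutation test of the list score (100000 resamples) beside it. A member counted as measured only where a kept probe carried its symbol, so a gene present under an accession alone would be missed. Spots left out as outliers were filled with their group's mean for camera and fry. The correlation across genes of both high minus low contrasts was set against 100 permutations of the labels within each set. Slide was tested with an F test in limma. ADIPOQ was also compared by an exact rank sum test on 44 arrays. Random draws used seed 1, and statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.

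The genes named were, for each contrast and direction, up to 10 with a symbol and the smallest p among those past the threshold, filled to 5 with those of smallest unadjusted p where fewer than 5 passed, and of each list described the up to 4 measured members of smallest p. CAPN1, CAPN2, CAPN3, CAST and MSTN were also to be given, and 0 of these 5 had a symbol on the array. The designs, the lists, this rule and most alternatives were set before the data were examined. They were normexp background correction (offset 50, with the median in place of the mean signal, which 4 files held), quantile normalisation, the authors' log2 matrix, no filter, a filter on all arrays, slide or the title number as a block, leaving out 8 arrays of another file layout, other rules for probes, array weights, eBayes with trend and robust, fits on the groups of a contrast, and leaving out each array.

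A fit without 3 arrays whose spot grid did not match was chosen after the data were seen, alone and with other settings, as was a list of the 11 mitochondrially encoded genes named in the files. The grid was checked in windows of 24 spot rows by 12 columns at shifts of up to 8 rows and 4 columns. Each window was compared with the mean log2 signal of the other arrays, the 3 left out of that mean. The fits were tested on simulated data built on the ES contrast, drawn as independent normal values without slide effects or genes that vary together. With 47 arrays and 20424 genes or probes, 1.2% of the genes given a log2 difference of 0.5 were called, 23.6% of those given 1 and 67.6% of those given 2. Of the calls, 6.68% were wrong. With 44 arrays and 20520, the shares called were 15.6%, 64% and 92%, and 3.48% of the calls were wrong. The number of arrays and the quality of single arrays, such as these 3, limit the precision.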

Results

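Muscle RNA of 47 steers was profiled on single-colour bovine arrays, 1 steer per array. The groups held 12 steers with high and 11 with low residual shear force among those judged after electrical stimulation (ES), and 12 with high and 12 with low residuals among those judged without stimulation (NES). A higher shear force means tougher meat. All muscle was taken before stimulation, so the ES and NES sets are different steers. Values are log2 signal relative to each array's 75th percentile, and differences are high minus low unless stated. Only genes with a symbol are named and most of the genes or probes tested have none.

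On 44 of the arrays the 75th percentile of intensity ran from 248 to 1054 (median 620), and 48.0% to 81.1% of probes were well above background (median 73.4%). These arrays had 0 saturated spots, and each had a median correlation of 0.934 to 0.979 with the other arrays. Probes well above background made up 71.8% ± 5.97 in ES high (SD, n = 11), 74.0% ± 4.34 in ES low (n = 10), 70.3% ± 6.94 in NES high (n = 11) and 69.3% ± 8.31 in NES low (n = 12). The other 3 arrays, ES high replicate 6, ES low replicate 5 and NES high replicate 5, had median correlations of 0.031, 0.0676 and 0.0185 with all others. On these 3 arrays 14.1% to 18.1% of spots were non-uniform, against at most 0.445% elsewhere, and 25.2% to 34.7% of probes were well above background. Only 6, 26 and 5 of 126 windows of spots on them matched best at their own position, against 126 of 126 on each of the other arrays. At the best shift their median correlation was still only 0.457 to 0.517, against 0.946 to 0.995 elsewhere. So at least part of their spot grids lay off the printed positions, and shifts in the tested range did not recover the rest. These 3 arrays stayed in the fits of 47 arrays, as designed. Each of the 5 contrasts is also given without them, a choice made after they were seen. Most single members of the lists are given with 47 arrays only.

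**Figure D1:**
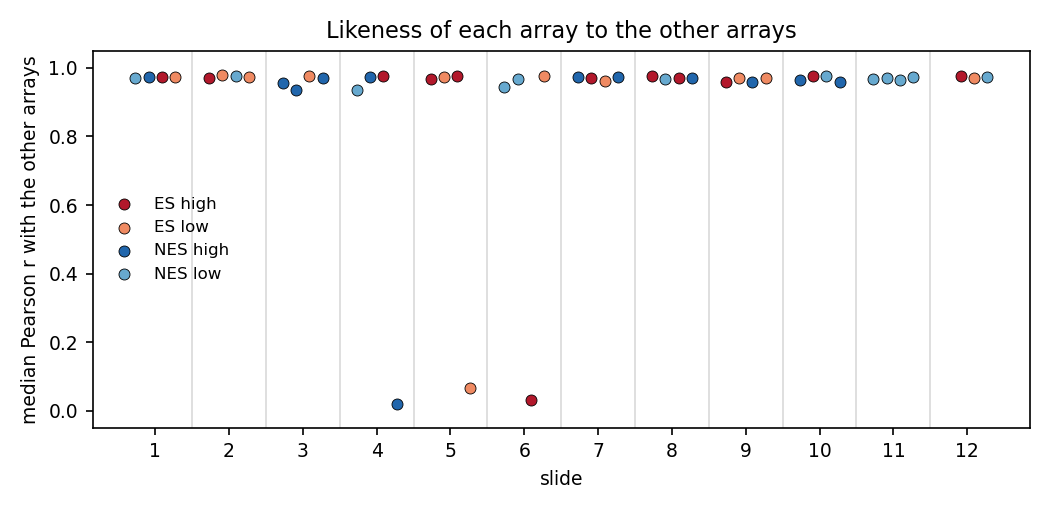
Median Pearson correlation of each array with the other arrays (vertical axis, no unit) by slide (horizontal axis, 12 slides), coloured by group. The 3 arrays with a misplaced grid lie between 0.0185 and 0.0676, and the other 44 between 0.934 and 0.979.

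The ES set addressed which genes differ at slaughter between steers whose stimulated meat had a high or a low residual shear force. KIF5C, a kinesin heavy chain that carries cargo along microtubules, had a signal of -1.52 ± 0.52 in ES high (SD, n = 12) and -2.92 ± 1.76 in ES low (n = 11), a difference of 1.40 ± 0.49 (SE, p = 0.00667). DUSP7, a phosphatase acting on MAP kinases, had a difference of 1.04, SPOCK2, a matrix proteoglycan, 0.96, the transcription factor FOXD1 1.02, and FSD1L 1.11. On the lower side stood SLC7A6, an amino acid transporter (-0.92 ± 0.34, p = 0.00977), the semaphorin receptor PLXND1 (-0.95), the cadherin CDH6 (-0.67 ± 0.28), the zinc finger factor GLIS2 (-1.25) and the adhesion receptor BAI1 (-0.68). None of these genes passed the adjustment, and single arrays weighed on some: GLIS2 had -0.17 without ES low replicate 5, DUSP7 0.55 and PLXND1 -0.60 without ES high replicate 6, and FOXD1 0.63 without ES low replicate 11. With limma, 0 of 20424 genes or probes had an adjusted p under 0.05 (smallest 0.9999), and 547 had an unadjusted p under 0.05 (255 higher, 292 lower), where 1021 would be expected by chance. With array weights the count was also 0, with 2715 unadjusted and a smallest adjusted p of 0.0526; trend and robust eBayes gave 0 and 570.

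Without the 3 arrays with a misplaced grid, ERBB4, a receptor for neuregulins, had the smallest p among genes with a symbol in the ES set, with -0.74 ± 0.59 in ES high (n = 11) against -1.62 ± 0.63 in ES low (n = 10), a difference of 0.88 ± 0.26 (SE, p = 0.00165). With all 47 arrays its difference was -0.10, but 0.39 with normexp background and 0.48 with the title number as a block, so its direction changed with the setting. KIF5C had a difference of 1.58 ± 0.51 (p = 0.00358), PANK1, a pantothenate kinase of coenzyme A synthesis, 0.82, the growth inhibitor OKL38 0.82, and the transcription factor HAND1 0.85. KIF5C was well above background on 41 of 44 arrays. Its lowest ES low steers, replicates 7, 6 and 11, had -6.30, -5.18 and -4.78, under the next at -3.26. The low values of a few steers therefore weighed on its difference in means in both fits. Lower values were those of the protease CAPN5 (-0.43 ± 0.15, p = 0.00744), KIAA0040 (-0.53), the endosomal protein WDFY1 (-0.83), the kinase PFTK1 (-0.70) and NPNT, a matrix ligand of integrins (-0.68). CAPN5 had an adjusted p of 0.0149 adjusted over the list alone, a list of 2 measured calpains, and 0.98 over all genes, but 0.02 ± 0.42 was its difference with all 47 arrays. The limma count was again 0 of 20520, with 807 unadjusted (369 higher, 438 lower, 1026 by chance) and a smallest adjusted p of 0.98; array weights gave 0 and 2697. On slides that held both ES groups, ERBB4 was lower in ES high on 0 of 6 and KIF5C on 1 of 6, with slide differences of 0.18 to 2.75 and -0.33 to 3.74. Each of these slides held only 1 or 2 steers per ES group. Both genes were named for their small p on the same arrays, so these directions are no independent evidence. With slide as a block and all 47 arrays, KIF5C had 1.52 and ERBB4 -0.29. The half-width of the 95% interval had a median of 0.784 with 47 arrays and 0.447 with 44.

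**Figure D2:**
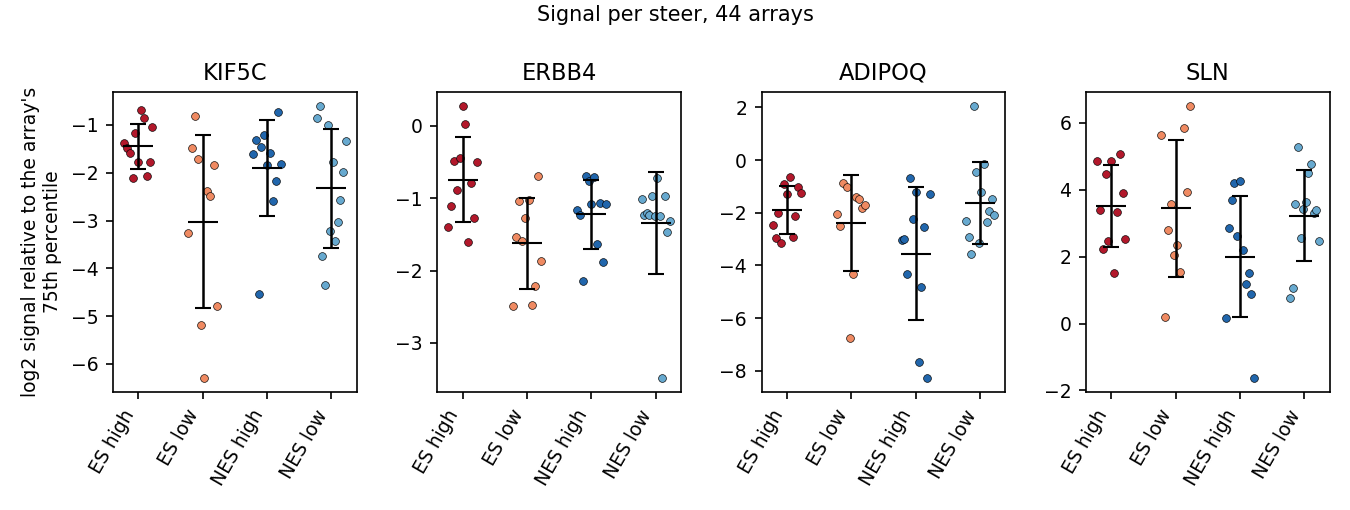
Log2 signal relative to the array's 75th percentile (vertical axes) of KIF5C, ERBB4, ADIPOQ and SLN in each of 44 steers by group, with mean and SD. ADIPOQ had -3.55 ± 2.53 in NES high and -1.63 ± 1.55 in NES low, with overlapping steers.

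The NES set asked the same of steers whose meat was judged without stimulation. Among the lower genes named by symbol, the widest differences were those of ADIPOQ, the adipocyte hormone adiponectin, and SLN, sarcolipin, a small inhibitor of the calcium pump of the sarcoplasmic reticulum. ADIPOQ had -3.55 ± 2.53 in NES high (SD, n = 11) and -1.63 ± 1.55 in NES low (n = 12), a difference of -1.92 ± 0.91 (SE, p = 0.0397). It was well above background on 42 of 47 arrays, and the lowest NES high steers, replicates 11 and 8, had -8.29 and -7.66, far under the next at -4.83. The group medians were -2.98 and -2.01, -0.97 apart, and a rank sum test on 44 arrays, chosen after the values were seen, gave p = 0.0908, so the low values of a few steers weighed on the difference in means. SLN had 1.76 ± 1.91 and 3.23 ± 1.36, a difference of -1.47 ± 0.79 (p = 0.0683). KIAA1632 (-0.33), the microtubule kinase MARK1 (-0.29) and the tight junction protein TJP1 (-0.38) were the other lower genes. Higher values were those of DSC2, a desmosomal cadherin (0.84 ± 0.32, p = 0.0121), the cell cycle phosphatase CDC25A (1.01), TBC1D4, which acts in insulin-stimulated glucose uptake (1.03), KIAA0564 (1.11) and the microtubule protein CLASP1 (0.97). The direction of TBC1D4 was reversed with the title number as a block. Without NES high replicate 5 CLASP1 had 0.41, KIAA0564 0.72 and TJP1 -0.18, and without NES low replicate 5 KIAA0564 had 0.68. None passed the adjustment: limma called 0 of 20424 (smallest adjusted p 0.9998), with 258 at an unadjusted p under 0.05 (208 higher, 50 lower) against 1021 by chance. Array weights gave 0 and 433, and trend and robust eBayes 0 and 262.

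With the 3 arrays left out, DSC2 (0.59 ± 0.21), ARMCX3 of the mitochondrial outer membrane (0.53), SPRY4, an inhibitor of receptor tyrosine kinase signalling (0.62), AMIGO3 (0.47) and ZNF687 (0.59) were on the higher side in the NES set. Lower were C9orf77 (-0.43), the endosome fusion protein RABEP1 (-0.39), ADIPOQ (-1.92 ± 0.72, p = 0.0107), the thymosin TMSL8 (-0.61) and DSU (-0.58). SLN had -1.23 ± 0.65 (p = 0.0663). ADIPOQ had an adjusted p of 0.0215 adjusted over the list alone, a list of 2 measured adipocyte markers, 0.0793 with all 47 arrays, and 0.9998 over all genes in both fits. Limma called 0 of 20520, with 570 unadjusted (280 higher, 290 lower); array weights gave 0 and 415. On the 4 slides with both NES groups, SLN was lower in NES high on 4, by -4.02 to -0.58, and ADIPOQ on 3, with -3.57 to 1.35. Each of these slides held only 1 or 2 steers per NES group. Both genes were named for their small p in this contrast, so these directions are no independent evidence. With slide as a block and 47 arrays, ADIPOQ had -1.48 and SLN -2.28.

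The mean of both sets pooled the ES and NES differences of the same arrays. A gene can stand out in this mean through 1 set alone, so the mean is no test of sharing. KIF5C came first among genes with a symbol, at 0.96 ± 0.34 (SE, p = 0.00771), with its wider difference in the ES set. Its signal was -1.805 ± 1.005 in NES high and -2.323 ± 1.243 in NES low (SD, n = 12 each). Behind it among the higher genes stood ARID5B, a chromatin regulator (0.70), C1orf182 (0.45), CDC25A (0.69) and DUSP7 (0.61, but 0.10 without ES high replicate 6). DUSP7 had 1.19 in NES high and 1.00 in NES low. The lower genes were the calcium pump ATP2B2 (-0.94), SLC7A6 (-0.56), monoamine oxidase A, MAOA (-0.49), the chloride cotransporter SLC12A2 (-0.33) and ANKFY1 (-0.36). ATP2B2 was well above background on only 14 of 47 arrays. In the fit of 44 arrays ACSL4, which activates long-chain fatty acids, had the smallest p among genes with a symbol (-0.25 ± 0.08, p = 0.00324), with RFX5, a factor for class II genes (-0.33), WDFY1 (-0.61), SLITRK6 (-0.69) and NPNT (-0.51). SLITRK6 was well above background on only 16 of 44 arrays. With each of the 47 arrays left out in turn, the ranges of ACSL4 (-0.18 to 0.0043) and NPNT (-0.33 to 0.12) crossed 0. On the higher side of that fit stood ARMCX3 (0.41), KIF5C (1.00 ± 0.35), ERBB4 (0.50), DSC2 (0.42) and CDC25A (0.60). ERBB4 had -1.22 in NES high and -1.34 in NES low, so its difference lay mainly in the ES set. For ARMCX3 the range with each of the 47 arrays left out in turn was -0.05 to 0.45. Limma called 0 with 47 arrays (306 unadjusted, 174 higher and 132 lower, smallest adjusted p 0.9998) and 0 with 44 (861 unadjusted, smallest adjusted p 0.984). With array weights the calls were 0 and 0, with 1452 and 1419 unadjusted.

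Whether the high minus low difference itself differed between the sets was tested as an interaction. BAI1 (-1.17 ± 0.41, p = 0.00636) and GLIS2 (-1.94 ± 0.71, but -0.92 without ES low replicate 5) had the smallest p among the lower genes with a symbol, followed by IER5L (-0.75), RASGRP3, an exchange factor for Ras (-1.40), and PFTK1 (-1.37). FSD1L (1.33 ± 0.57), PLEKHF1 (1.53), C9orf77 (0.83), the amino acid transporter SLC43A2 (1.18) and PERQ1 (2.14-fold) were on the higher side. With 44 arrays these were CSDC2 (0.88), RAPGEF6 (1.34), HAND1 (1.15), DSU (0.91) and GLCE, an enzyme of heparan sulfate synthesis (1.00), and on the lower side AMIGO3 (-0.74), BAI1 (-0.95), IER5L (-0.67), KIAA0040 (-0.68) and BZRAP1 (-0.60). RAPGEF6 was well above background on only 15 of 44 arrays. Limma called 0 in both fits, with 347 (145 higher, 202 lower) and 565 unadjusted and smallest adjusted p of 0.9996 and 0.9954; array weights gave 0 and 0, with 1108 and 1074 unadjusted. Across genes, which are not independent replicates, the ES and NES differences had a correlation of 0.000754 (permutation p = 1), within the -0.51 to 0.55 of 100 permutations. With 44 arrays it was 0.036 (permutation p = 0.91).

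The ES and NES sets were then compared with each other, which sets different steers side by side and not stimulated with unstimulated muscle. GDAP1, a protein of the mitochondrial outer membrane, had a difference of 0.48 ± 0.17 (ES minus NES, SE, p = 0.00632), and 0.49 ± 0.15 (p = 0.00178) without the 3 arrays. Other higher genes were the ubiquitin ligase scaffold CUL5 (0.26), the microtubule-severing SPAST (0.33, and 0.22 without ES high replicate 6), the histone methyltransferase SUV420H1 (0.40, and 0.26 without NES low replicate 5) and the inositol phosphate kinase IHPK3 (1.27). BZRAP1 (-0.39 ± 0.14), EPB41L5 (-0.38), the retinoic acid receptor RARG (-0.55), the myosin MYO1D (-0.56) and NRP2 (-0.42) were lower. In 44 arrays AMIGO3 came first among genes with a symbol (-0.49 ± 0.13, p = 0.000717), with PEX5L (-0.68), NOTCH2 (-0.38), BZRAP1 (-0.39) and GLIPR1 (-0.57) on the lower side and the repressor BCL6 (0.53), C14orf2 (0.26), the sodium channel subunit SCN4B (0.76) and the RNase XRN1 (0.27) on the higher. With each of the 47 arrays left out in turn, C14orf2 ran from -0.31 to 0.21, so its direction changed with the arrays used. Limma called 0 in both fits (341 and 782 unadjusted, smallest adjusted p 0.9997 and 0.9947), and array weights 0 and 0 (843 and 820 unadjusted). In each contrast 1 or 2 of the 10 genes named with 47 arrays were also named with 44.

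Of the 62 genes in the sarcomere and cytoskeleton list, 8 were measured under a symbol. These 8 were, on balance, lower in high-residual steers over both sets with 47 arrays. The mean difference of the 8 measured members was -0.24, with 7 lower and 1 higher, and camera gave an adjusted p of 0.0315. The call was lost with an estimated correlation (adjusted p = 0.242) and with fry (adjusted p = 0.492), and the permutation p of the list score was 0.243. The members of smallest p were DTNA, a dystrobrevin of the dystrophin complex (-0.31 ± 0.18), plectin, PLEC1 (-0.56), vinculin, VCL (-0.39), and nebulette, NEBL (-0.31). Without the 3 arrays the mean difference was -0.07, with 4 members lower and 4 higher and an adjusted p of 0.336, so the call rested on them. With 44 arrays the mean was -0.15 in the ES set, 7 lower and 1 higher (camera adjusted p = 0.202, permutation p of the score 0.0301, unadjusted), and 0.01 in the NES set, 4 lower and 4 higher (adjusted p = 0.920). Leaving out ES high replicate 6 alone gave an adjusted p of 0.341, and leaving out NES high replicate 5 gave 0.229; without NES low replicate 2, ES low replicate 3, NES high replicate 7, ES low replicate 10, NES high replicate 11 or ES low replicate 11 it lay between 0.0502 and 0.0587. In the ES set the list score was 2.32 ± 0.87 (SD, n = 12) against 2.59 ± 0.40 (n = 11), with a camera adjusted p of 0.154, and in the NES set 2.45 ± 0.85 against 2.66 ± 0.14 (adjusted p = 0.131). Leaving out ES low replicate 5 brought the ES value to 0.0185, and leaving out NES high replicate 2 or 3 brought the NES value to 0.0449 and 0.0158. With slide as a block the differences were -0.17 in the ES set and -0.49 in the NES set (adjusted p 0.482 and 0.0300), and the score was lower in high steers on 5 of 7 slides and on 3 of 4. With 44 arrays the score was lower on 4 of 6 and on 2 of 4, and the smallest adjusted p of the 3 tested lists with that block was 0.553 in the ES set and 0.904 in the NES set. With 44 arrays DTNA had -0.38 ± 0.16 over both sets (p = 0.0247, 0.197 adjusted over the list alone).

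Potassium channel genes (6 measured) had a mean difference of -0.29 in the ES set, 5 lower and 1 higher, with KCNT2 at -0.93 ± 0.53, KCNMB4 at 0.61, KCTD12 at -0.45 and KCNQ1 at -0.66 (camera adjusted p = 0.159). In the NES set their mean was 0.11 (adjusted p = 0.910). With 44 arrays the means were -0.15 in the ES set and -0.01 in the NES set (camera adjusted p 0.203 and 0.920). The 6 measured genes of growth signalling and myogenesis had means of 0.14 and -0.06 (adjusted p 0.154 and 0.215), among them FRAP1, the kinase of the mTOR complexes, at 0.48 in the ES set. MEF2D, a muscle transcription factor, had 0.25 there and 0.41 with 44 arrays. The growth list had means of 0.04 in the ES set and 0.05 in the NES set with 44 arrays (camera adjusted p 0.203 and 0.920). Of the 11 mitochondrially encoded genes, a list chosen from the names in the files, 10 were lower in NES high with a mean of -0.35 (adjusted p = 0.0611, and 0.403 with an estimated correlation). With 44 arrays that mean was 0.07. The number of members past the adjustment, over all genes and adjusted over the list alone, was 0 in each tested list.

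Of 37 fixed lists, 3 had at least 5 measured members, 25 had 1 to 4 and 9 had 0 (lysosomal cathepsins, oxidative phosphorylation, slow fibre, interferon, serine protease inhibitors, lymphocyte, neutrophil, erythroid and class II). Of the 94 oxidative phosphorylation genes, for example, 0 had a symbol on the array. These counts depend on which probes carried a symbol and do not show that the genes were undetected. Among genes of protein breakdown, CAPN6 had 0.43 ± 0.29 and the ubiquitin ligase NEDD4 -0.47 ± 0.28 in the NES set. The apoptosis genes BCL2L1 and BIK had 0.69 and -1.09 in the ES set, the autophagy gene ATG5 0.42 in the NES set, and ATG12 -0.38 in the ES set. In energy metabolism PFKFB3, which makes the activator of phosphofructokinase, had 1.28 ± 0.94 in the ES set and -0.42 in the NES set, glycogen synthase GYS1 0.59 and 0.02, and PDK4, which restrains pyruvate dehydrogenase, 0.63 and -0.32. With 44 arrays PDK4 had 0.69 ± 0.30 in the ES set (p = 0.0257). The fast fibre light chain MYLPF had -1.15 ± 0.81 in the NES set, and the calcium pump ATP2B4 -0.68 ± 0.29 in the ES set (p = 0.0264), though -0.21 with 44 arrays. None of these passed the adjustment.

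Members of the fixed matrix lists did not pass the adjustment in either set. COL22A1 had 0.99 ± 1.09 and the collagen crosslinking enzyme LOXL2 0.47 ± 0.37 in the NES set, while P4HA1, MMP15, HSPG2 and MATN2 lay between -0.45 and just under 0 in both sets. Stress and clock genes did not pass either: FOSB -0.32, MAFF -0.37, PER2 0.02, CSNK1E 0.04, SESN2 -0.62, DDIT3 0.35, EIF2AK3 -0.37 and BAG3 -0.07 in the ES set. The ribosomal protein genes RPL13A and RPL39 had 0.18 and 0.36. Among markers of other cells, also with no member past the adjustment over all genes, the fibroblast markers PDGFRA and PDGFRB had 0.41 and -0.19 in the ES set and -0.21 and 0.03 in the NES set, the endothelial ROBO4 -0.13 and -0.23, and the pericyte marker RGS5 0.33 and -0.47. NOTCH3, listed for pericytes and for satellite cells, had -0.57 and 0.09, the macrophage markers LYZ and MRC1 0.24 and 0.02 in the ES set, and the nerve markers NGFR, ERBB3 and EGFL8 lay between -0.15 and 0.34 in both sets. Of the adipocyte markers, ELOVL6 had 0.31 ± 0.61 and -0.06 ± 0.59, beside ADIPOQ.

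SYT4 and RUNX1, chosen after their values were seen, fell into separate levels among steers. SYT4, a synaptotagmin of vesicle traffic, was low in 7 of 44 steers and high in 37, with no array between, by 2 of its 3 probes. By the third the same 7 steers were the lowest, at -9.13 to -8.37, but the others ran from -7.42 to -3.34, and the levels were not clearly apart. The high steers had a median of 0.46 and -2.58 by the probes with separate levels, and the 7 low steers, not well above background by either, were 2 ES high, 2 ES low, 2 NES high and 1 NES low. RUNX1, a transcription factor that denervated muscle is known to raise, was high in 5 steers by its first probe and in 6 by the other, 5 of them the same, with medians 14.6-fold and 29.5-fold apart. Over 68 such probes, 0 splits were associated with group at an adjusted p under 0.05 by Fisher's exact test.

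**Figure D3:**
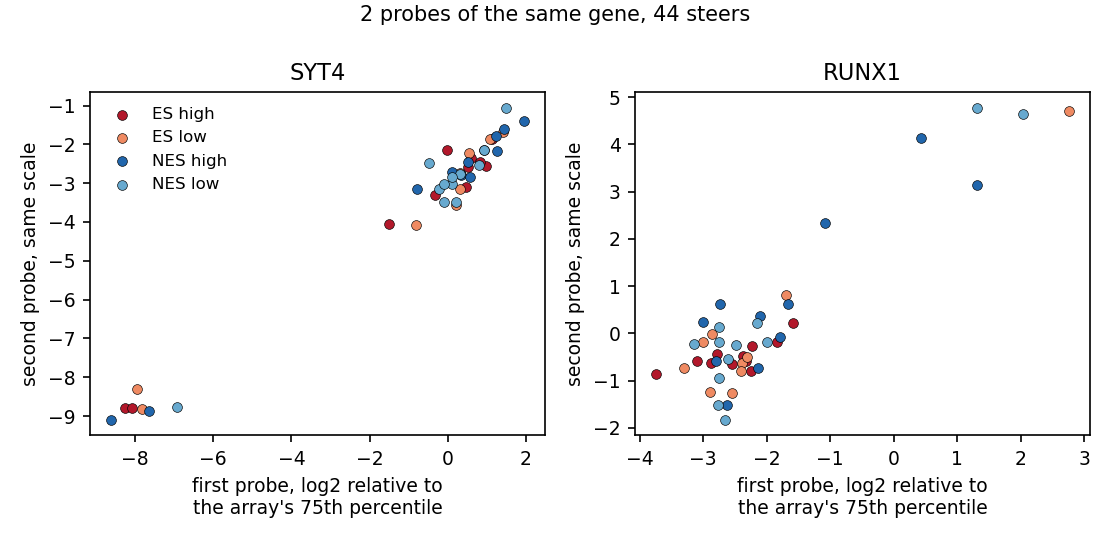
First against second probe of SYT4 and RUNX1 with separate levels (2 of 3 SYT4 probes), both in log2 relative to the array's 75th percentile, in 44 steers coloured by group. For SYT4 the same 7 steers are low by both probes shown, and for RUNX1 5 steers are high by both.

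Arrays lay on 12 slides, 11 of them with 4 arrays and 1 with 3, and slide 11 held 4 NES low arrays and no other group. With group in the model, slide explained the signal of 607 genes or probes at an adjusted p under 0.05 (2660 unadjusted) with 47 arrays and of 3817 (6529 unadjusted) with 44. Slides and the steers' title numbers overlapped: with 44 arrays the first 2 digits of the title number alone gave 2665, slide with those digits in the fit 274, and the digits with slide in the fit 68. With slide as a fixed block, limma called 0 in all 5 contrasts, with 836 unadjusted in the ES set and 302 in the NES set, and with 44 arrays 1068 and 325.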

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

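In this part, leaving out the 3 arrays with a misplaced grid and the list of mitochondrial genes were chosen after the result was seen. The count of 0 genes in each of the 5 contrasts held under every alternative that was run and with each of the 47 arrays left out. The smallest adjusted p over all settings was 0.0526, with array weights in the ES set; for the difference between sets it was 0.118, with the title number block and 44 arrays. The direction of named genes was the same in 520 of the planned comparisons with an alternative and reversed in 25. Unadjusted counts left out 1 array at a time ran from 418 to 861 in the ES set and from 134 to 429 in the NES set. Without a filter on dim probes the unadjusted counts were 524 and 253. Only 197 probes or genes were well above background on all 47 arrays, the 3 with a misplaced grid included, with 1 and 2 unadjusted. No paired analysis was possible because all steers differ and each gave 1 array.

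The list count for the ES set was 1 with normexp (adjusted p 0.00122), and for the NES set 1 with normexp (0.0150), without a filter (0.0282) and with slide as a fixed block (0.0300). These calls used camera at the preset correlation. An estimated correlation, run on the main values only, gave smallest adjusted p of 0.249 in the ES set and 0.248 in the NES set. Over both sets it was 0 with the title number block (0.416), without the 8 arrays of another layout (0.0806), with array weights (0.194), an estimated correlation (0.242), fry (0.492) and the permutation test, and 0 without the 3 arrays by camera (0.336), estimated correlation (0.482), fry (0.549), permutation (0.566) and slide block (0.591). Each array left out in turn gave 0 to 1 lists in each. The slide effect was 117 with normexp, 247 with quantile normalisation, 378 with the authors' matrix, 312 without the 8 arrays and 3817 without the 3.

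With the 3 arrays left out, ERBB4 in the ES set turned to 0.88, CAPN5 to -0.43, NPNT over both sets to -0.51 and C14orf2 between sets to 0.26; the mitochondrial list to -0.0013, 0.072 and 0.035 (ES, NES, both), and in the NES set the sarcomere list to 0.0074, the potassium list to -0.014 and the growth list to 0.050. Windows of spots on those arrays matched at other positions than their own, so part of their values were read at other spots.

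For the reversals that follow, the cause was not tested. With normexp these were ERBB4 0.39 and CAPN5 -0.14 (ES), DSU 0.17 (NES), WDFY1 0.12 and SLITRK6 0.13 (both), RAPGEF6 -0.047 (difference), C14orf2 0.00138, the mitochondrial list -0.093 (ES), potassium 0.092 and growth -0.038 (both). With quantile normalisation ARMCX3 had -0.24 (NES) and -0.00759 (both), DSU -0.14 (difference), potassium -0.14 (NES) and growth -0.040 (both). With the authors' matrix SLC7A6 had 0.12 (both), ARMCX3 -0.044, potassium -0.070 (NES) and growth -0.014 (both). Without a filter potassium had 0.010 (both). With slide as a fixed block the values were CAPN5 -0.00185, ARMCX3 -0.64 (NES) and -0.088 (both), DSU 0.45 (NES) and -0.72 (difference), ACSL4 0.072, GLCE -0.15, C14orf2 0.058, growth -0.020 (both) and the correlation across genes -0.0789, which was -0.109 with the filter on all arrays. With the title number block TBC1D4 had -0.21, ERBB4 0.48, NPNT -0.11, C14orf2 0.00306 and the mitochondrial list -0.25 (ES). Without the 8 arrays ACSL4 had 0.021 and the mitochondrial list -0.059 (ES). With array weights the mitochondrial list had -0.10 (ES), potassium -0.026 and growth 0.0052 (NES).

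With each array left out in turn, ranges that crossed 0 were: correlation across genes -0.274 to 0.283, ACSL4 -0.18 to 0.0043, ARMCX3 -0.050 to 0.45 (both) and -0.036 to 0.53 (NES), C14orf2 -0.31 to 0.21, CAPN5 -0.50 to 0.10, DSU -0.16 to 0.58 (difference) and -0.58 to 0.058 (NES), ERBB4 -0.27 to 0.74 (ES), NPNT -0.33 to 0.12, growth -0.12 to 0.050 (NES) and -0.021 to 0.095 (both), mitochondrial -0.49 to 0.43 (ES), -0.47 to 0.033 (NES) and -0.43 to 0.036 (both), potassium -0.014 to 0.20 (NES) and sarcomere -0.31 to 0.0074 (NES).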

Other observations

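For the probes with separate levels and the other splits of the samples, the tests in this part were chosen after the result was seen. The tests on slide likeness were set before their results. For ADIPOQ this holds for the ratio of the genes that followed it and for the fit with slide as a block. The rank sum test was added later, and the correlations of ADIPOQ with ELOVL6 and HIF3A are not counted as set before.

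Some genes lay at separate levels in different steers, with no tested association with the shear force groups. Among 35441 probes with signal on 44 arrays, 68 probes of 57 genes or accessions had 2 levels at least 1.5 log2 apart with 5 or more steers on each side, where normal draws gave 4. Such draws have no background floor, and many low levels were not well above background. The 4 is therefore no full measure of what the floor can give. Of these probes 5 carried a symbol, 2 of SYT4, 2 of RUNX1 and 1 of LOC653444. The high steers of the first RUNX1 probe were exactly the high steers of 4 genes or accessions in this set, RUNX1 included. The group association of the RUNX1 probes had a p of 0.659 and 0.368 by Fisher's exact test.

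Of the 68 probes, 34 had another probe of the same gene. For 25 of the 34 probes the compared probe put more of the same steers on its low side than chance, by a hypergeometric test. The 2 SYT4 probes with separate levels were such a pair (adjusted p = 1.27e-07), and each counts among the 25. This argues against a base difference under 1 probe alone, but not where both probes cover the same bases, which was not examined. For 9 probes the compared probe did not, and a base difference under the probe, in steers of crossed descent, may account for some of these. At least 1 of the 9, however, had a further probe of its gene with separate levels. The 6 steers low by that further probe were also the 6 lowest by this one (adjusted p = 5.35e-07 by the same test). Further probes of the others were not compared. For 67 probes at least 3 slides held both levels, which argues against slide as the only source. A part for slide was not tested and stays open. A probe with 31 low and 13 high steers had both levels on only 4 of 12 slides, and another with 26 low and 18 high had them on all 12. An inherited difference in the gene's expression or copy, or the state of the muscle, stays open and was not tested.

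ADIPOQ was named for its small unadjusted p in the NES contrast and did not pass the adjustment (limma adjusted p = 0.9998). Further tests of its NES difference on the same arrays are therefore no independent evidence. ADIPOQ, well above background on 40 of 44 arrays, was lower in NES high by a mean of -1.92 (permutation p = 0.0355) but by a median of -0.97 (rank sum p = 0.0908, a test added later), against a mean of 0.51 in the ES set (permutation p = 0.464). A smaller share of fat cells in the muscle piece may account for this: 15 genes or accessions followed ADIPOQ within groups (r above 0.7, at most 3 in 100 shuffles), and their differences were a median 1.02 times what their slopes on ADIPOQ gave. Another source that moves these genes together would give the same ratio, and only 1 of them, HIF3A, has a symbol. Whether the others include adipocyte markers was not examined. ELOVL6, the only other listed adipocyte marker that carried a symbol (2 of 33 did), had -0.34 ± 0.28. With slide as a block the difference was -1.97, which argues against slide. 1 of the 15, an accession without a symbol (r = 0.956), is a transcript of ADIPOQ itself, so 14 other genes or accessions followed, all 14 lower in NES high, with a median of 0.998 times.

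Across the 44 steers ADIPOQ correlated with ELOVL6 (r = 0.506, permutation p = 0.00045; rho = 0.569, permutation p = 0.0003), and r was 0.637 without the 2 steers farthest from the median ADIPOQ. With HIF3A, r was 0.752 (permutation p = 1e-05, the smallest the permutations can give; rho = 0.749, permutation p = 0.0001) and 0.698 without 2. These are 2 of 3 relations computed, with Benjamini-Hochberg p of 0.00045 and 1.5e-05; HIF3A was picked for following ADIPOQ, so its r is no independent evidence, and the third, with the mean of the 15, is left out because ADIPOQ itself is among them.

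Arrays of 1 slide resembled each other beyond their groups: on 44 arrays the first component held 14.4% of the variance, of which slide accounted for 82.8% and group for 3.88%, while of components 2 and 3 (8.34% and 7.77%) slide accounted for 39.9% and 30.4%, where random placement gives 25.6% on average. Pairs on 1 slide whose steers' title numbers differed in the first 2 digits had a mean correlation of residuals 0.184 above pairs sharing neither, and pairs on different slides with the same digits 0.165 above (each permutation p = 0.0001, the smallest that 10000 permutations can give). So slide and the origin of steers with nearby numbers may each contribute, and what the numbers stand for is not stated in the labels. With array brightness as a covariate 4072 genes or probes had a slide effect, against 3817 without it, which argues against brightness as the main source of that effect. Brightness still accounted for 15.56% of component 1, 14.15% of component 2 and 1.97% of component 3, so a part for it is not excluded. No biological explanation of the slide pattern was tested.

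Other splits of the same steers, 100 for each result with the real split counted, were fitted to ask whether chance gives as much. A real count of 0 is met by any split, so it says nothing on chance: for genes past the adjusted threshold with 47 arrays, 100 of 100 splits gave as many as the real 0 in each of the 5 contrasts, where the highest other count was 0 in the ES contrast, 1 in the NES contrast, 1 over both sets, 0 for the difference and 0 for ES against NES. The same holds for the lists of the ES set and the NES set, with a real count of 0, 100 of 100 splits and a highest other of 1 and 2. For lists over both sets 16 of 100 splits gave as many as the 1 list over both sets (highest other 1), so chance cannot be excluded for the sarcomere list. The slide effect of 607 was reached by 3 of 100 placements on slides, the highest other giving 2270, and with 44 arrays the 3817 by 1 of 100, the real one, with a highest other of 2, so chance is excluded there.

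With 44 arrays, as many genes at an unadjusted p under 0.05 as the real split were given by 29 of 100 splits in the ES set (807, highest other 2827), 97 in the NES set (570, highest other 3374), 51 over both (861, highest other 3359), 73 for the difference (565, highest other 3244) and 46 for ES against NES (782, highest other 2537). Chance cannot be excluded for any of these 5. Past the adjusted threshold, other splits of the 44 arrays called up to 421 genes in the ES set and 53 in the NES set. The highest other counts were 3 over both, 562 for the difference and 1 for ES against NES, and each real count was 0. Single splits that call several times the real count may reflect a structure among the steers or arrays, such as slide, or genes that vary together, which was not tested.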
